A study of Mus musculus with 2 samples.

How the data were processed

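Total RNA of dissected ureters from NMRI mouse embryos at E14.5 was measured on 2 two-colour Agilent arrays, each with 1 Gata6cKO and 1 control RNA (4 RNA samples in all). Per the labels' protocols, RNA was isolated with peqGOLD RNAPure and turned into Cy3- or Cy5-labelled cRNA with a low-input amplification kit. The labels do not say whether an RNA came from 1 embryo or a pool, nor whether samples shared a litter. Each p-value of a single gene therefore rests only on the spread between these samples, which the fit below pools largely across genes. Both arrays lay on 1 slide and were scanned together, per the file headers.

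For each array the deposited scanner file gives, per the file headers, the raw mean intensity of every spot and the median intensity of its local background in each dye, before any correction. The same file holds a processed intensity, which the authors obtained with Agilent Feature Extraction 10.7.3.1 (version per the submitters' processing notes) after detrending and a lowess dye correction, and its log10 ratio of Cy5 over Cy3, per the file headers. The deposited series values give a score for each probe and array. Comparison with the scanner files showed that this score is a signed linear fold of Gata6cKO over control: no value lies between -1 and 1 and both column medians are 1. After conversion to log2, its values had a Pearson r of 0.987 and 0.983 with the log2 ratios of the processed intensities, across the probes kept below. How the authors summarised the 4 spots of a probe for that score is not stated in the labels. There were 0 unused per-sample columns.

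The main analysis started from the raw intensities in R 4.3.3 with limma 3.58.1, data.table (1.17.8) and statmod 1.5.0. Background was corrected with normexp (offset 50), and the log2 ratios were normalised within each array by loess, with control and outlier spots at weight 0. Spots not marked as outliers were averaged per probe. A probe was kept where at least 3 of its 4 spots were well above background in the Gata6cKO channel or in the control channel on both arrays, which left 26200 of 39429 probes. The probe with the highest mean intensity stood for each gene, and 5046 genes had more than 1 kept probe. Among genes that passed, 193 had more than 1 kept probe, and in 8 of them the probes had opposite signs. No spot was saturated. Signal over background limits dim genes: where 1 genotype was not well above background on either array, the change was given as a bound, at least N-fold, which concerned 93 genes in Gata6cKO and 81 in control.

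Probe names, gene names and probe coordinates were taken from the scanner files, whose coordinates are on mm9 per the file headers. Symbols were brought up to date with a RefSeq gene table of assembly GRCm38.p6, used for names only: 28328 probes matched by accession, 1602 symbols were updated, and 31971 probes had a symbol that the table lists. Genes are reported under these symbols.

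The log2 ratio of Gata6cKO over control was fitted with lmFit and eBayes in limma, with the sign turned on the dye-swapped array, so that each array is its own pair. The fit has 1 residual degree of freedom beside 11.9 prior ones (prior SD 0.162). P-values were adjusted by Benjamini-Hochberg over 19801 genes, with a threshold of 0.05, and a rule of at least 2-fold on both arrays was given beside it. Of 26 gene lists, all were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the lists. Camera called 11 lists with the preset correlation and none with an estimated one (smallest adjusted p = 0.536), and fry called none (smallest adjusted p = 0.219). The last 2 rest on 1 residual degree of freedom and could hardly call any list. Their lack of calls therefore does not show that the lists did not move. The camera and fry p-values are two-sided. With the preset correlation, camera sets the genes of a list against all other genes, as nearly independent units. The size of that p-value therefore does not measure how well the samples repeat each other. Of the listed genes, 13 stand in more than 1 list. Medians of the called lists were at the 0th or 100th percentile of 10000 random lists matched on intensity. The smooth muscle list, which camera did not call, was at the 0th percentile too, so this percentile does not set the called lists apart.

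The named genes were Gata6, the other measured GATA genes and Tbx18, the 15 largest falls and 15 largest rises among genes that passed and moved the same way on both arrays (leaving out clone and placeholder names such as those ending in Rik), and up to 4 members of each list with the smallest p plus Acta2, Tagln, Myh11, Myocd, Bmp4, Ptch1, Axin2, Aldh1a2 and Upk2. The lists tested with camera, the named-gene rule, the limma, camera and fry tests and the alternative settings were fixed before the data were examined. The additional gene lists and the tests under Other observations were not among them, and that part states when they were chosen. Gata6os, Pcp4, Stra6, Lef1, Sfrp2, Wnt4, Dkk1, Ednrb, Msln and the genes that only the closing section names lie outside that rule and were chosen after their values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

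Background correction, normalisation, the gene fit and camera were tested on simulated spot signals with the real intensities and dye curve. Of 50 genes shifted by 0.3 on the log2 scale, 2 were called in the simulated comparison of Gata6cKO with control over 19801 genes. Of 50 shifted by 0.6, 43 were called, and all 50 of those shifted by 1 and all 50 of those shifted by 1.5. Among 19601 unchanged genes, 14 were called. With no change at all, 0 genes and 0 of 26 lists were called, and when the 17 retinoic acid genes were shifted by 0.3 on the log2 scale, camera called that list and no other. The simulation draws genes as independent, so it does not test the effect of correlation between them. It also takes the probe filter and outlier marks from the real arrays. Its noise follows the variance prior that the fit assumes, so neither the filter nor that prior was tested.

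The alternatives were no background subtraction, Agilent's processed intensities, median centring, scaling between arrays, no filter, a filter on all 4 channels, the mean of a gene's probes, the deposited series values, an intensity trend in the variance prior, separate channels, an adjusted p under 0.1, an estimated correlation, fry, and each array alone. Splice forms, probes without a gene name as a group and linked alleles were not analysed.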

Results

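Gene expression was compared between mouse ureters with a conditional loss of Gata6, called Gata6cKO, and control ureters at E14.5. Gata6 encodes a zinc finger transcription factor. The Gata6cKO embryos carried 2 floxed Gata6 copies and a cre recombinase in the Tbx18 locus, a gene of the mesenchyme around the ureteric epithelium, and the control embryos carried at least 1 floxed copy and no cre in their labels. The study asks which transcripts are deregulated when Gata6 is deleted in cells with a history of Tbx18 expression. Per the labels, every Gata6cKO RNA and no control RNA carried cre. The loss of Gata6 therefore cannot be told apart from effects of cre or of the Tbx18 copy that holds it. Total RNA of 4 samples was hybridised in pairs to 2 two-colour arrays. On the replicate 1 array both RNAs came from males and the Gata6cKO RNA was labelled with Cy5. On the replicate 2 array both came from females and the dyes were exchanged. The median spot signal lay at 232 (Cy3, control) and 425 (Cy5, Gata6cKO) on replicate 1, and at 224 (Cy3, Gata6cKO) and 442 (Cy5, control) on replicate 2, over median local backgrounds of 24, 85, 23 and 83. Between 67.2% and 68.5% of the spots were well above background in each channel. The number of arrays limits the precision. Xist, the transcript that silences an X chromosome in females, had a processed signal of 2286 and 2130 in both RNAs of the female array and stayed at background on the male array. The Y-linked Ddx3y had a signal of 1511 and 1546 in both RNAs of the male array and stayed at background on the female array.

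In the RNA labelled Gata6cKO, 16 of 30 measured urothelial markers fell and none rose, and of 20 markers of neurons and glia 14 rose and 1 fell. Of 34 smooth muscle genes 4 fell and 2 rose, and of 17 retinoic acid genes 4 rose and 1 fell. Myocd, the coactivator that switches on smooth muscle genes, fell by 1.33 ± 0.12 on the log2 scale (moderated SE, n = 2 arrays), a 2.51-fold lower level. Aldh1a3, an enzyme that makes retinoic acid, rose by 2.33 ± 0.11, a 5.04-fold higher level. Upk1b, a uroplakin of the urothelial surface, fell by 1.98 ± 0.12, a 3.94-fold lower level. Nefm, a neurofilament subunit of neurons, rose by 1.83 ± 0.11, a 3.56-fold higher level. Of 19801 genes tested with limma, 465 were lower and 436 higher at an adjusted p under 0.05, and all 901 moved the same way on both arrays. With 2 arrays, a gene with opposite signs on them could not pass this fit, so the shared sign is no separate support. At least 2-fold on both arrays, 42 genes were lower and 37 higher, and all of these also passed the test. The median change among the genes that passed was 1.52-fold for the lower and 1.56-fold for the higher ones.

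The Gata6 probe on the array (chromosome 18, 11085039 to 11085097, mm9) gave a higher signal in the RNA labelled Gata6cKO. Its log2 ratio was 0.65 ± 0.12 (n = 2 arrays; limma adjusted p = 0.00612), with 0.85 on the male and 0.46 on the female array. Whether this probe lies in the floxed part of the gene was not settled, since no exon map was used, so its rise checks nothing about the labels. The call was lost under 3 other settings, with an adjusted p of 0.625 with median centring, 0.0712 with no filter on dim probes and 0.0520 with separate channels, at a log2 ratio of 0.59, 0.65 and 0.65. Gata6os, a transcript beside Gata6 on the opposite strand that was chosen after its values were seen, was 2.63-fold higher (1.39 ± 0.12, n = 2 arrays; limma adjusted p = 1.98e-05). Among the other GATA factors, none passed: the log2 ratio was -0.15 for Gata1, 0.05 for Gata2, -0.06 for Gata3 and 0.05 for Gata5, and Gata2 turned to -0.02 with median centring. Gata4 was not above background and was not tested. Tbx18, of which the Gata6cKO embryos carry 1 copy with cre per their labels, had a log2 ratio of -0.20 ± 0.14 (limma adjusted p = 0.861) and did not pass, with 0.09 on the male and -0.50 on the female array.

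**Figure D1:**
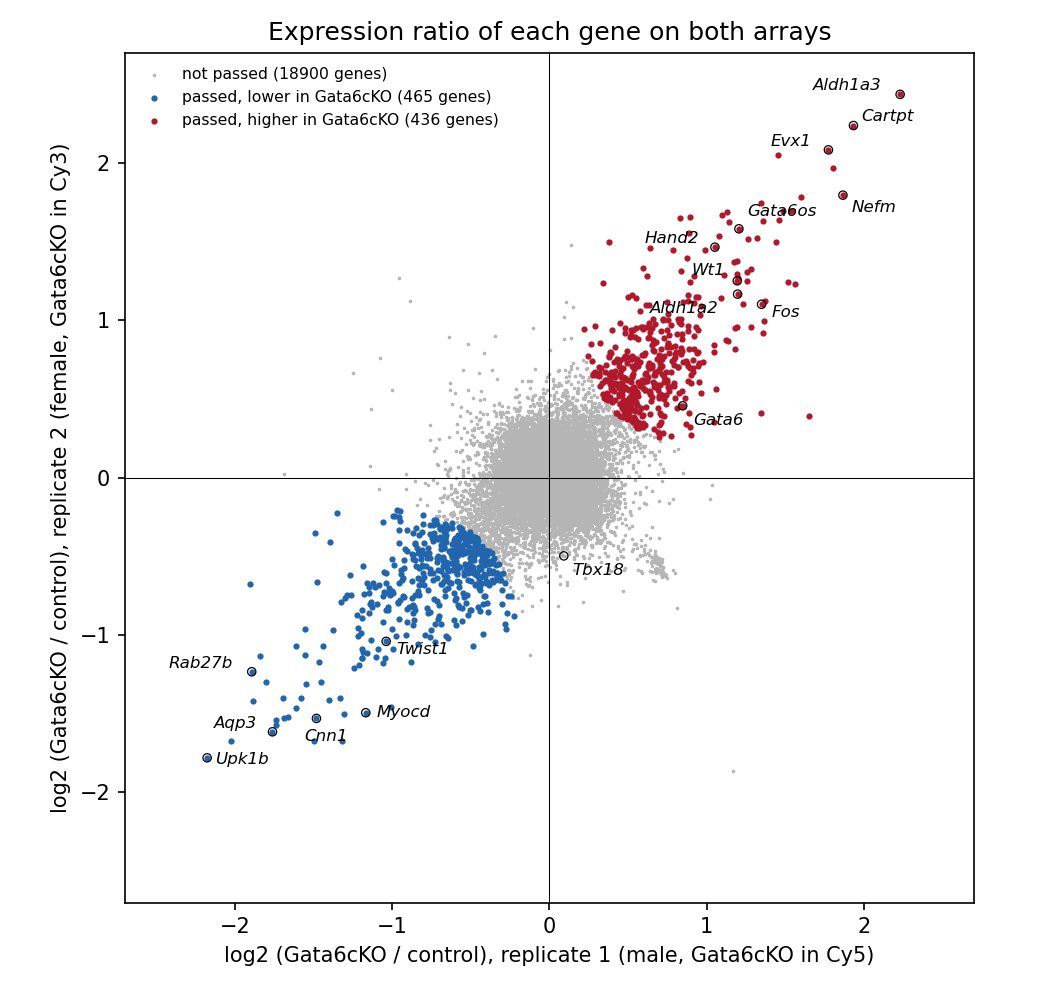
Each point is 1 of the 19801 genes tested, with the log2 ratio of Gata6cKO over control on the replicate 1 array (x axis) against that on the replicate 2 array (y axis); blue and red points are the 465 lower and 436 higher genes that passed. Aldh1a3 lies at 2.23 and 2.44 and Upk1b at -2.18 and -1.78. No gene that passed has opposite signs on the arrays, since such a gene could not pass this fit.

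Smooth muscle genes moved in both directions. Of 34 measured members of the smooth muscle list, 4 fell, 2 rose and 28 did not pass, and adjusted over the list alone 5 fell and 3 rose. The falls were Cnn1, the actin-binding protein calponin, at a log2 ratio of -1.51 ± 0.11, Myocd at -1.33 ± 0.12, Actg2, a smooth muscle actin, at -1.09 ± 0.11, and Myh11, the smooth muscle myosin heavy chain, at -0.81 ± 0.11 (n = 2 arrays each). The rises were Synpo2, an actin-binding protein, at 0.87 ± 0.11, and Pcp4, a calmodulin-binding protein, at 0.82 ± 0.11. Acta2, the most widely used smooth muscle actin marker, had a log2 ratio of -0.29 ± 0.11 (limma adjusted p = 0.242), and Tagln, a smooth muscle actin-binding protein, one of -0.15 ± 0.14, and neither passed. The list median was -0.10 and camera gave an adjusted p of 0.160, 0.648 with an estimated correlation. With median centring or an intensity trend in the prior, the list passed camera, at an adjusted p of 0.0324 and 0.0266. On the same arrays 6 of 15 skeletal muscle markers rose, with a list median of 0.41, which was 0.48 on the male and 0.19 on the female array (camera adjusted p = 1.54e-10, and adjusted p = 0.536 with an estimated correlation).

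Of 17 measured genes of retinoic acid signalling, 4 rose, 1 fell and 12 did not pass, and adjusted over the list alone 7 rose and 1 fell. Beside Aldh1a3, Aldh1a2, another enzyme of retinoic acid synthesis, rose by 1.18 ± 0.11 (2.27-fold), and Cyp26b1, an enzyme that degrades retinoic acid, by 0.57 ± 0.12. Stra6, a membrane receptor for the retinol carrier, rose by 0.59 ± 0.14, with 0.90 on the male and 0.27 on the female array. Rbp4, the retinol carrier itself, fell by 0.65 ± 0.14 on the log2 scale, with -0.96 and -0.33 on the arrays. The median was 0.21 and the camera adjusted p = 4.80e-08, and adjusted p = 0.536 with an estimated correlation. On the same arrays 14 of 20 markers of neurons and glia rose, with a list median of 0.69, and 16 of 30 urothelial markers fell, with a list median of -0.49.

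Of 26 measured genes of WNT signalling, 7 rose, 3 fell and 16 did not pass, and adjusted over the list alone 9 rose and 3 fell. Rspo1, a secreted enhancer of WNT signalling, rose by 1.55 ± 0.11 (2.93-fold), the WNT ligands Wnt9b and Wnt5a by 0.83 ± 0.11 and 0.82 ± 0.12, and Sp5, a transcription factor that WNT signals induce, by 0.81 ± 0.11. The falls were Lef1, a nuclear partner of beta-catenin, at -0.58 ± 0.12, the WNT antagonist Sfrp2 at -0.51 ± 0.11 and the ligand Wnt4 at -0.47 ± 0.11, with -0.26 at its other kept probe. Another WNT antagonist, Dkk1, rose by 0.88 ± 0.17, with 1.34 on the male and 0.41 on the female array. Axin2, a common readout of WNT activity, had a log2 ratio of 0.23 ± 0.11 and did not pass. The camera adjusted p was 1.54e-04 for the list, and adjusted p = 0.536 with an estimated correlation. The list median was 0.11 over both arrays, 0.20 on the male and 0.12 on the female array. Rspo1 also stands in the mesothelium list, and the lists of neurons and glia, skeletal muscle and nephron and kidney stroma had medians of 0.69, 0.41 and 0.19 on the same arrays.

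Of 17 measured genes of FGF signalling and ERK feedback, 4 fell, none rose and 13 did not pass, and adjusted over the list alone 5 fell. The growth factors Fgf10 and Fgf7, which mesenchyme sends to epithelium, fell by 0.76 ± 0.12 and 0.64 ± 0.11 on the log2 scale, the phosphatase Dusp4, a feedback inhibitor of ERK, by 0.46 ± 0.11, and the transcription factor Etv1 by 0.48 ± 0.12, with -0.28 on the male and -0.67 on the female array. The camera adjusted p was 0.00511 for the list, and adjusted p = 0.536 with an estimated correlation. On the same arrays 9 of 22 immediate early genes, some of which ERK signals induce, rose, with a list median of 0.31. BMP, Hedgehog and Notch lists did not pass camera (adjusted p = 0.548, 0.370 and 0.530). In the BMP list, the antagonist Nog (0.70 ± 0.11) and the receptor Bmpr1b (0.54 ± 0.12, with 0.36 on the male and 0.71 on the female array) rose, the ligand Bmp5 (-0.60 ± 0.11) fell and 18 of 21 did not pass, Bmp4 among them at 0.28 ± 0.11, and adjusted over the list alone 3 rose and 3 fell. In the Hedgehog list, the co-receptor Cdon rose by 0.47 ± 0.11 (0.30 at its other kept probe, and not passed as the mean of both) and 16 of 17 did not pass, among them the pathway target Ptch1 at -0.24 ± 0.12, and adjusted over the list alone 2 rose and 1 fell. In the Notch list, the ligand Jag2 (-0.51 ± 0.11) and the modifying enzyme Lfng (-0.50 ± 0.13, with -0.24 on the male and -0.75 on the female array, not passed when genes were taken as the mean of their probes) fell and 16 of 18 did not pass, and adjusted over the list alone 2 fell and 1 rose.

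Of 28 measured transcription factors of the mesenchyme, 5 rose, 1 fell and 22 did not pass, and adjusted over the list alone 8 rose and 2 fell. Hand2, a basic helix-loop-helix factor that sympathetic neurons also express, rose by 1.26 ± 0.12 (2.39-fold), and the distal homeobox gene Hoxd13 by 1.25 ± 0.12 (2.37-fold). Twist1, a basic helix-loop-helix factor of mesenchymal cells, fell by 1.04 ± 0.11 on the log2 scale, a 2.05-fold lower level. The camera adjusted p was 2.52e-05, and adjusted p = 0.536 with an estimated correlation, on arrays where the list of neurons and glia had a median of 0.69. The list median was 0.14 over both arrays, 0.23 on the male and 0.15 on the female array. In the list of fibroblast layers, 5 of 20 measured members fell, 2 rose and 13 did not pass, and adjusted over the list alone 6 fell and 3 rose. Among them the matrix proteins Dpt (-1.20 ± 0.11) and Lum (-0.62 ± 0.11) and the growth factor Ptn (-0.67 ± 0.11, with -0.24 at its other kept probe) fell, and the surface peptidase Dpp4 (0.62 ± 0.11) rose. Camera gave an adjusted p of 0.0424 for that list, and adjusted p = 0.556 with an estimated correlation. Its median was -0.14 over both arrays, -0.21 on the male and -0.02 on the female array. That call was also lost with Agilent's processed signals, the mean of a gene's probes, the deposited series values and separate channels, at an adjusted p of 0.0744, 0.0711, 0.0577 and 0.0601. In the extracellular matrix list, the secreted protein Postn fell by 0.52 ± 0.13 on the log2 scale, with -0.74 on the male and -0.30 on the female array, and 33 of 34 members did not pass, the same count adjusted over the list alone (camera adjusted p = 0.785).

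**Figure D2:**
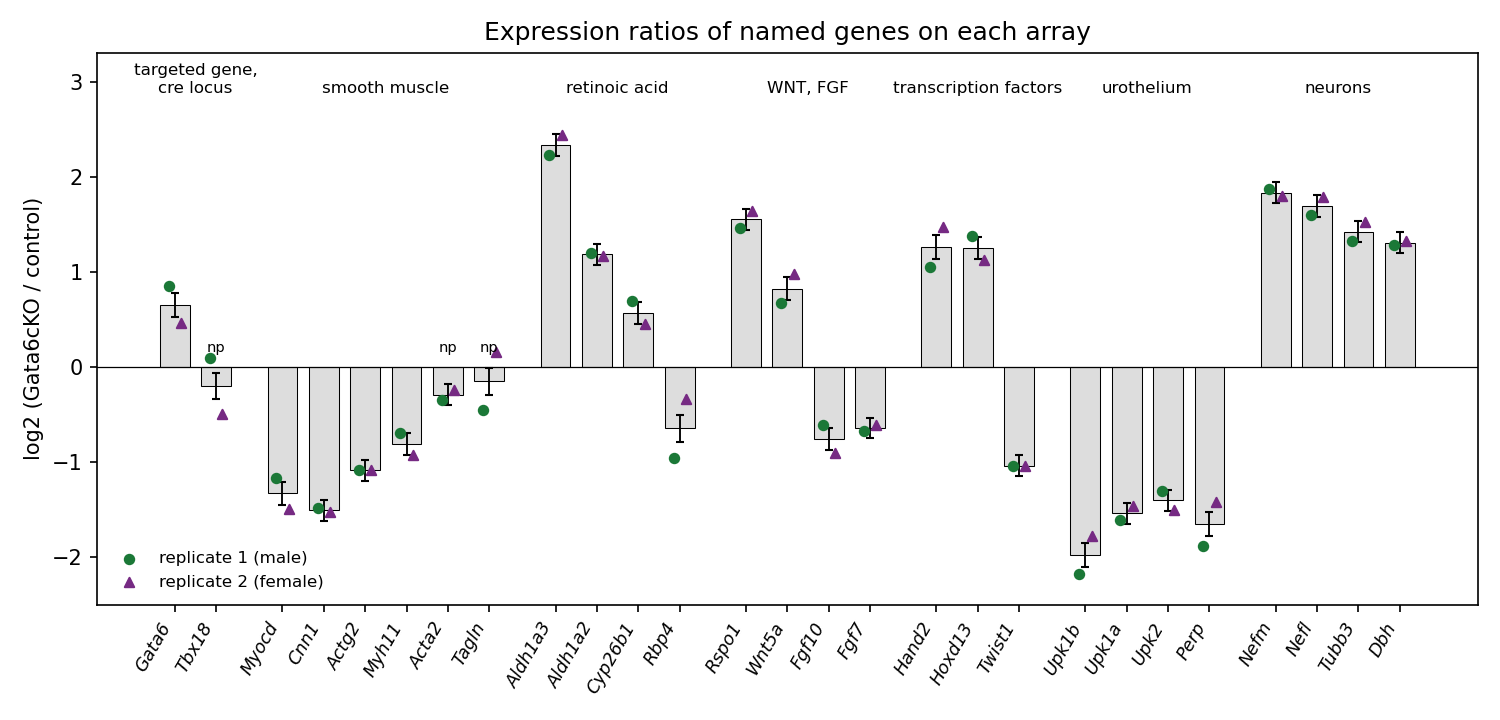
Bars show the log2 ratio of Gata6cKO over control as the mean of both arrays with the moderated standard error, circles the replicate 1 array and triangles the replicate 2 array; np marks genes that did not pass. Myocd lies at -1.17 and -1.49 on the arrays and Cyp26b1 at 0.69 and 0.45, whereas Tagln lies at -0.46 and 0.15.

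The urothelium list held the most falls of all 26 lists. Of 30 measured members, 16 fell, none rose and 14 did not pass, and adjusted over the list alone 22 fell. Besides Upk1b, the uroplakins Upk1a and Upk2 fell by 1.54 ± 0.11 (2.91-fold) and 1.40 ± 0.11 (2.65-fold) on the log2 scale, and Perp, a junction protein of stratified epithelia and a p53 target, fell by 1.65 ± 0.13 (3.14-fold). The median was -0.49 and the camera adjusted p = 3.21e-32, and adjusted p = 0.536 with an estimated correlation. Beside Upk1b, Upk1a, Perp and Cnn1, the 15 largest falls held Fa2h, a fatty acid hydroxylase (-1.85, 3.60-fold), Aqp3, a water and glycerol channel (-1.69, 3.22-fold), Sprr1a, a precursor of the cornified envelope (-1.66, 3.15-fold), and Hpgd, a prostaglandin-degrading enzyme (-1.59, 3.01-fold). Car3, a carbonic anhydrase (-1.64, 3.11-fold), Shisa2, an inhibitor of WNT and FGF receptor transport (-1.59), Rab27b, a GTPase of secretory vesicles (-1.56, 2.95-fold), Serpinb5 (-1.55, 2.93-fold), Aldh3b2 (-1.55, 2.92-fold), Kif5b, a kinesin heavy chain (-1.49, 2.82-fold), and Tmprss13, a membrane serine protease (-1.49, 2.80-fold), were the rest of them. The limma adjusted p of the 15 genes lay between 2.11e-06 for Upk1b and 2.69e-05 for Rab27b. The Kif5b probe lies within 10 Mb of the Gata6 probe on chromosome 18, and linked alleles were not analysed.

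In the list of neurons and glia, 14 of 20 measured members rose, 1 fell and 5 did not pass, and adjusted over the list alone 15 rose and 1 fell. Nefl, a neurofilament subunit, rose by 1.69 ± 0.11 (3.23-fold), Tubb3, the neuronal beta-tubulin, by 1.42 ± 0.11 (2.68-fold), and Dbh, the enzyme that makes noradrenaline, by 1.30 ± 0.11 (2.47-fold), whereas the endothelin receptor Ednrb fell by 0.57 ± 0.14 on the log2 scale, with -0.27 on the male and -0.86 on the female array. The median was 0.69 and the camera adjusted p = 3.88e-25, and adjusted p = 0.536 with an estimated correlation. Among the 15 largest rises were also the neuropeptide gene Cartpt (2.09, 4.24-fold), the microtubule regulators Stmn4 (1.88, 3.69-fold) and Stmn3 (1.49, 2.82-fold), Tlx2, a homeobox gene of autonomic neurons (1.55, 2.92-fold), and Gdnf, a ligand of the Ret receptor (1.59, 3.01-fold). Evx1, a homeobox gene, was not well above background in control and was at least 3.68-fold higher. Adamts18, a secreted protease (1.75, 3.37-fold), Col8a1, a short-chain collagen (1.61, 3.06-fold), Slc38a5, an amino acid transporter (1.41, 2.66-fold), and Alkal2, a ligand of the ALK receptor (1.39, 2.63-fold), completed the 15, which like the falls leave out genes known only by a clone or placeholder name. The limma adjusted p of the 15 genes lay between 6.11e-07 for Aldh1a3 and 3.63e-05 for Slc38a5.

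Markers of several other cell types moved with genotype. In the skeletal muscle list, 6 of 15 measured members rose and 9 did not pass, and adjusted over the list alone 8 rose. The embryonic myosin Myh3 rose by 1.04 ± 0.11, the myosin light chain Myl1 by 0.81 ± 0.11, and Myog, a master regulator of muscle differentiation, by 0.79 ± 0.11, and the list had a median of 0.41 (0.48 on the male and 0.19 on the female array) and a camera adjusted p of 1.54e-10 (adjusted p = 0.536 with an estimated correlation). In the erythroid list, 5 of 16 fell and 11 did not pass, and adjusted over the list alone 13 fell. Slc4a1, the anion exchanger of red cells, fell by 0.54 ± 0.12 and Ahsp, which binds alpha globin, by 0.46 ± 0.11 on the log2 scale, and the list had a median of -0.38 and a camera adjusted p of 1.16e-12 (adjusted p = 0.536 with an estimated correlation). The globins Hbb-b1 (-0.47 ± 0.11) and Hbb-b2 (-0.71 ± 0.14, with -0.42 on the male array) also passed, but near-identical copies leave their values uncertain. In the list of the nephron and kidney stroma, 4 of 19 rose and 15 did not pass, and adjusted over the list alone 6 rose, with Wt1, a transcription factor of the nephron and the mesothelium, at 1.22 ± 0.11, Cited1 at 0.50 ± 0.11, Lrp2, a receptor of the proximal tubule, at 0.47 ± 0.12, and Lhx1 at 0.46 ± 0.11. The Lhx1 value rests on the brighter of its 2 kept probes, and the other had a log2 ratio of -0.02, so that the mean of both did not pass. The camera adjusted p of that list was 1.29e-04, and adjusted p = 0.556 with an estimated correlation.

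Mesothelial markers split. Of 8 measured, Upk1b, Msln and Upk3b fell, Rspo1 and Wt1 rose and 3 did not pass, the same counts adjusted over the list alone. Upk3b was at least 2.17-fold lower, since the Gata6cKO signal was not well above background, and Msln, named because the list holds few genes, had a log2 ratio of -1.49 ± 0.15. Camera gave an adjusted p of 0.302 for the mesothelium list, 0.0159 with median centring and 0.0104 with an intensity trend in the prior. It gave 0.731 with an estimated correlation and 0.934 with the filter on all 4 channels. The lists of endothelium (21 measured), pericytes (12), macrophages and leukocytes (19), cartilage (13) and gonad and adrenal (14) did not pass camera, at adjusted p = 0.433, 0.433, 0.160, 0.466 and 0.571. Their genes that passed were the endothelial receptor Tek (-0.55 ± 0.11), the pericyte potassium channel Kcnj8 (0.51 ± 0.12, with 0.33 and 0.70 on the arrays), the coagulation factor F13a1 (-0.61 ± 0.13, with -0.87 and -0.35 on the arrays), the cartilage link protein Hapln1 (-0.48 ± 0.11), and in the gonad and adrenal list Dhh (0.79 ± 0.11) and Inhbb (-0.67 ± 0.12). Adjusted over each list alone, these counts were the same.

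**Figure D3:**
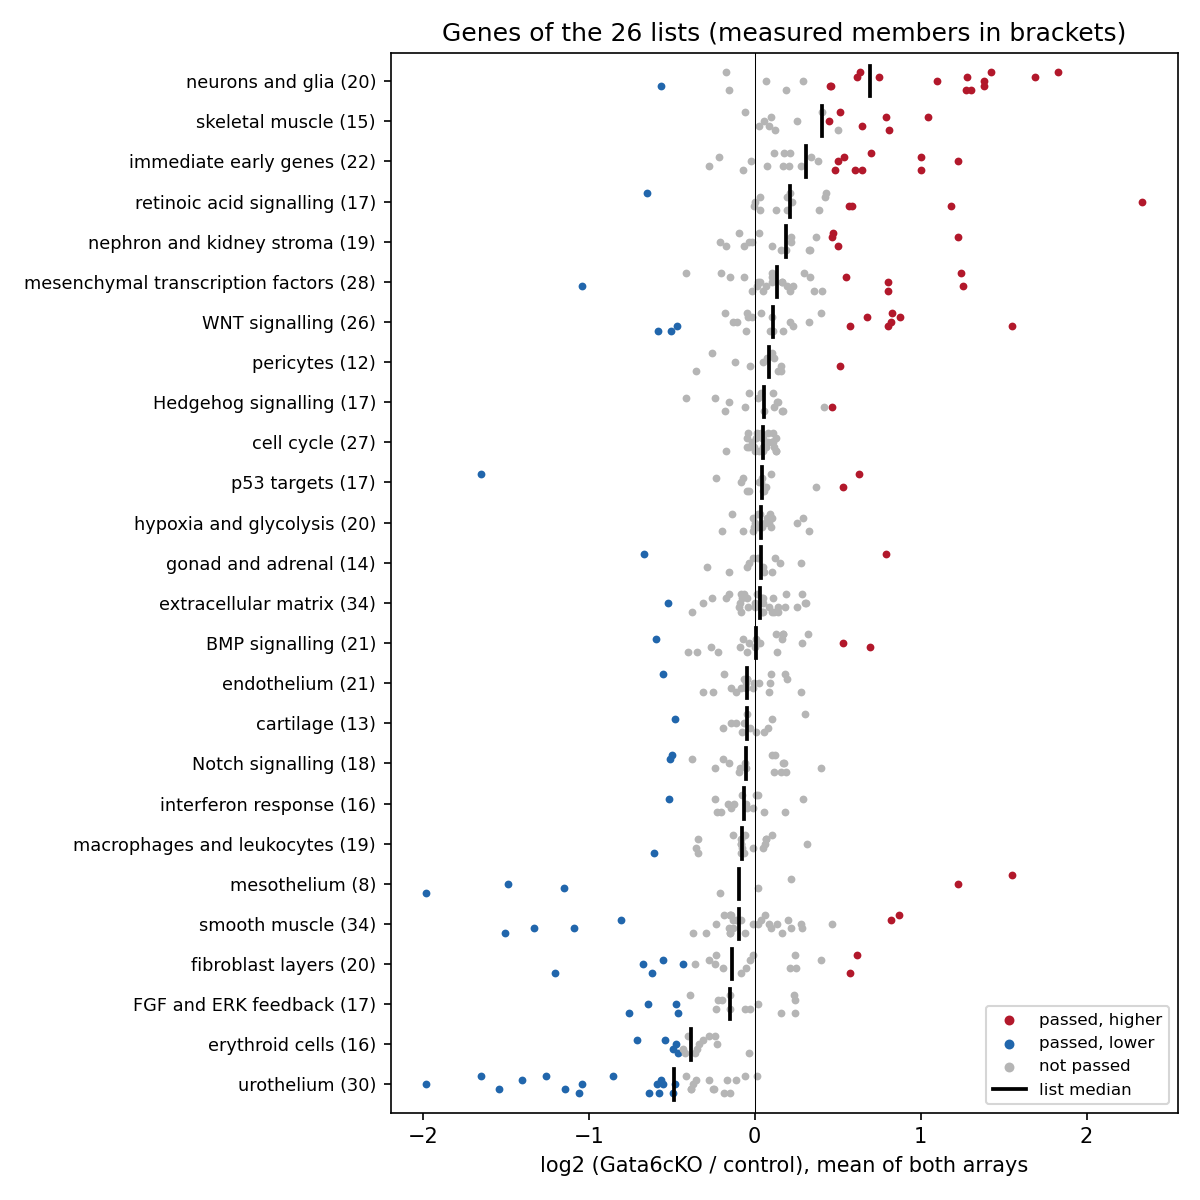
Points show the log2 ratio of Gata6cKO over control of each measured gene in the 26 lists, as the mean of both arrays, and black lines the list medians; red and blue points passed the test over all genes. The list medians lie between -0.49 for the urothelium and 0.69 for neurons and glia.

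Immediate early genes, which cells switch on within minutes of stimulation or stress, moved with genotype. Of 22 measured members, 9 rose, none fell and 13 did not pass, and adjusted over the list alone 12 rose and 1 fell. The transcription factors Fos, Fosb and Egr1 rose by 1.23 ± 0.12, 1.00 ± 0.12 and 1.00 ± 0.12, and the cytokine signalling inhibitor Socs3 by 0.65 ± 0.11. The median was 0.31 and the camera adjusted p = 8.22e-12, and adjusted p = 0.536 with an estimated correlation. None of the 27 measured cell cycle genes and none of the 20 of hypoxia and glycolysis passed limma at an adjusted p under 0.05, over all genes or adjusted over the list alone (camera adjusted p = 0.302 and 0.280). Of 17 measured p53 targets, the cell cycle inhibitor Cdkn1a (0.63 ± 0.11) and the death receptor Fas (0.53 ± 0.12) rose, Perp fell and 14 did not pass, and adjusted over the list alone 3 rose and 1 fell (camera adjusted p = 0.498; the median was 0.04 and the mean -0.01). The antiviral gene Rsad2 fell by 0.52 ± 0.11 on the log2 scale and 15 of 16 interferon genes did not pass, the same count adjusted over the list alone (camera adjusted p = 0.203).

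When the signs were instead set so that dye bias and any sex difference in the response would add up, limma called 0 genes, with a smallest adjusted p of 0.928, and 689 genes had an unadjusted p under 0.05, against 2250 for the genotype. In that fit the changes with genotype enlarge the spread, so its 0 calls do not show that such differences were absent. Across genes, which are not independent replicates, the log2 ratios of both arrays had a Pearson r of 0.412 and a Spearman rho of 0.0877, and 48.8% of all genes had the same sign on both. The calls depended on the dye correction, with 100 lower and 90 higher genes under median centring in place of the intensity-dependent curve, while the genes at least 2-fold changed on both arrays then numbered 40 lower and 38 higher. A sex difference and a dye difference in the response to genotype could not be told apart, with 1 array per sex and dye order.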

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

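For the results in this part, the male array (replicate 1) and the female array (replicate 2) lay on opposite sides of 0, and the value is the male minus the female log2 ratio. The difference was not tested for any of them. Over all genes tested, 51.2% had opposite signs on the arrays, so opposite signs alone are no sign of a difference. Sex, dye order and array are confounded, since each sex was measured on 1 array with 1 dye order, so a sex difference stays open as untested.

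Among the GATA factors, which bind the same DNA motif, the difference was -0.34 for Gata1 (-0.32 on the male and 0.02 on the female array), 0.26 for Gata2 (0.18 and -0.08) and -0.64 for Gata3 (-0.38 and 0.26). Tbx18, the locus that carries cre, differed by 0.59 (0.09 and -0.50). Tagln, a smooth muscle actin-binding protein, differed by -0.61 (-0.46 and 0.15). The replication licensing factor Cdc6 differed by -0.46, the proliferation marker Mki67 by -0.28 and the spindle motor Kif11 by 0.44. The antiviral gene Oas1a differed by -0.55. None of these genes passed in the fit over both arrays, in which a gene with opposite signs could not pass.

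For whole lists, the difference between the arrays' medians was 0.19 for Hedgehog signalling (0.15 and -0.04), 0.20 for extracellular matrix (0.15 and -0.06), -0.30 for macrophages and leukocytes (-0.21 and 0.09) and 0.14 for cartilage (0.04 and -0.10). It was -0.0709 for p53 targets (-0.02 and 0.05), 0.24 for hypoxia and glycolysis (0.17 and -0.06) and -0.26 for the interferon response (-0.20 and 0.05). None of these 7 lists passed camera in the fit over both arrays.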

How the results depend on the processing

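All alternatives were planned before the data were examined, and the fit with the slide as a block was not run because both arrays lie on 1 slide. The fit of log ratios is paired, since each array pairs a Gata6cKO and a control RNA, and the separate-channel fit is the one without that pair. With 1 array no test is possible, so each array alone gives values only: the Gata6 log2 ratio ranged from 0.46 to 0.85, the genes at least 2-fold lower from 54 to 95 and higher from 54 to 79, since 1 array asks less than 2. Among named genes, 7 moved by more than the spread without replicate 1 and 2 without replicate 2. The counts of 465 lower and 436 higher genes became 100 and 90 with median centring, 229 and 248 with no filter on dim probes (29875 genes tested), 795 and 672 with the deposited series values, and 267 and 275 with separate channels. All 901 genes were among the calls without background subtraction, and 189 of them among the calls with median centring. The 42 and 37 genes at least 2-fold lower and higher became 40 and 38 with median centring, 89 and 101 with Agilent's processed signals and 79 and 85 with the deposited series values. The share of higher genes stayed between 45.8% and 52.0%, against 48.4%. Gata6 had an adjusted p of 0.625 with median centring (log2 ratio 0.59), 0.0712 with no filter (0.65) and 0.0520 with separate channels (0.65), over a range from 7.60e-04 to 0.625. Gata2, which did not pass, reversed to -0.018 with median centring. Among named genes, 42 lost their call with median centring, 25 with no filter and 24 with separate channels. Camera's adjusted p for smooth muscle became 0.0324 with median centring and 0.0266 with an intensity trend, and for mesothelium 0.0159 and 0.0104. Fibroblast layers lost the call with Agilent's processed signals (0.0744), the mean of a gene's probes (0.0711), the deposited series values (0.0577) and separate channels (0.0601). With an estimated correlation from 1 residual degree of freedom, adjusted p was 0.536 for immediate early genes, WNT, retinoic acid, FGF and ERK, mesenchymal transcription factors, urothelium, erythroid cells, neurons and glia, and skeletal muscle, and 0.556 for fibroblast layers and nephron and kidney stroma. With fry, it was 0.387 for immediate early genes, 0.362 for WNT, 0.219 for retinoic acid, 0.441 for mesenchymal transcription factors, 0.495 for fibroblast layers, 0.330 for nephron and kidney stroma, and 0.328 for FGF and ERK, urothelium, erythroid cells, neurons and glia, and skeletal muscle. The cause was not tested except where fewer arrays or more genes show it. Signal over background limits dim genes, of which 93 and 81 have only a bound.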

Other observations

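In this part, only the test on glial genes was written down before its result was seen. The tests on list medians per array, Hox genes, pan-epithelial genes and Tbx18, the additional gene lists, the genes named here and the windows around the targeted loci were chosen after the result was seen.

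Some distal Hox genes rose beside Hoxd13. Of 8 measured genes of Hox paralog groups 10 to 13 without Hoxd13, 4 rose, none fell and 4 did not pass, and adjusted over the list alone 5 rose, with Hoxc11 at 0.79 ± 0.12, Hoxd12 at 0.68 ± 0.12, Hoxd11 at 0.55 ± 0.11 and Hoxd10 at 0.47 ± 0.12 (log2, n = 2 arrays). Of 26 measured genes of groups 1 to 9, 1 rose, and adjusted over the list alone 4 rose. Of 27 pan-epithelial genes, 6 fell and 21 did not pass, and adjusted over the list alone 13 fell, with a median of -0.27, and the adhesion molecule Cdh1 fell by 0.64 ± 0.12 on the log2 scale, whereas Epcam stood at -0.19 ± 0.12 and did not pass. Of 9 measured basal cell genes, 4 fell, among them the laminin chains Lamb3 (-1.17 ± 0.12) and Lama3 (-0.58 ± 0.11) and the integrin Itgb4 (-1.02 ± 0.13), whereas the basal regulator Trp63 (-0.15 ± 0.13) did not pass. Ihh, a Hedgehog ligand, fell by 1.34 ± 0.12, Aspn, a small matrix proteoglycan, by 1.38 ± 0.11, and Klf5, an epithelial transcription factor, by 0.86 ± 0.11 on the log2 scale.

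Genes near the targeted loci were counted, without a test of the difference. Within 10 Mb of the Tbx18 probe on chromosome 9, 11 of 109 genes passed (10.1%), and within 10 Mb of the Gata6 probe on chromosome 18, 8 of 83 (9.64%), against 897 of 19660 genes with coordinates (4.56%). D030062O11Rik, beside Tbx18, had a log2 ratio of 1.47 ± 0.11, and 9130001E16Rik, beside Gata6, one of 0.94 ± 0.11. These genes, which prompted the look, and Gata6os are in the counts, whereas Gata6 and Tbx18 are left out. Kif5b, among the 15 largest falls, also lies in the window around Gata6. Linked alleles of the targeted strains were not analysed.

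For the neuronal markers that were higher in the RNA labelled Gata6cKO, a dye bias would give opposite signs on the 2 arrays, but the smaller of the medians of the list of neurons and glia was 0.73 ± 0.24 (bootstrap SE, 20 genes), which argues against dye as the whole cause. More distal tissue in the Gata6cKO samples cannot be told apart from other sources: Hox genes of groups 10 to 13 without Hoxd13 lay 0.33 ± 0.14 above those of groups 1 to 9 on the log2 scale, but by 0.51 on the male and 0.04 on the female array. The medians of the list of neurons and glia were 0.73 and 0.74 on these arrays, and those of 23 neuronal genes outside that list 0.34 and 0.32. Whole autonomic ganglia in the dissected tissue cannot be told apart from other sources. Written beforehand, ganglia were to put the median of the glial genes above 0.3. The median of 16 glial genes, 7 of which the list of neurons and glia also holds, was 0.19 ± 0.08 and did not meet this. Beside the median of 0.35 of 23 independent neuronal genes, it was also not low enough to meet the prediction for their absence. Ngfr stands in both the glial and the independent neuronal set. Of the 16 glial genes, Dhh (0.79), Sox10 (0.46), Foxd3 (0.45) and Ngfr (0.44) rose, Ednrb (-0.57) and Mbp (-0.47) fell and 10 did not pass. Of the 23 independent neuronal genes, 10 rose, 12 did not pass, among them Snap25 at 0.02 and Syp at 0.04, and the synaptic gene Syt1 fell by 0.97 on the log2 scale. A rise of neuronal genes by the loss of Gata6 stays open, untested.

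The median log2 ratio of the urothelium list was below 0 on both arrays, and 16 of its 30 measured members passed as lower in the RNA labelled Gata6cKO. A dye bias is argued against as the whole cause, since the smaller of the medians of the urothelium list on the arrays was -0.48 ± 0.08 (30 genes). A smaller share of epithelial cells of every kind would lower all epithelial genes alike, but the median of 27 pan-epithelial genes lay 0.77 ± 0.31 above that of the 15 other genes of the urothelium list on the log2 scale. These genes thus did not fall alike. Of the 27, however, 15 also stand in the urothelium list, which was split after its values were seen. The difference therefore does not settle whether a smaller share was the whole cause. Fewer urothelial cells beside other epithelia, and a smaller epithelial share behind the pan-epithelial median of -0.27, stay open. A change of the urothelium with the loss of Gata6 stays open, untested.

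The Gata6 probe was higher, not lower, in the RNA labelled Gata6cKO. It is the only kept probe of the gene, so no other Gata6 probe could be compared. Genotype labels exchanged on both arrays cannot be told apart from a probe outside the deleted part, since the Tbx18 log2 ratio of -0.20 ± 0.14, with 0.09 and -0.50 on the arrays, lies below 0 by less than 2 SE. If the copy with cre gave no Tbx18 signal, an exchange would put Tbx18 above 0.5, and correct labels would put it as far below 0. The mean of -0.20 lies at neither, and whether that copy gives a signal was not measured. Tbx18 therefore does not decide whether the labels were exchanged. A rise of the RNA of the recombined locus stays open as well, and every direction in the text rests on the labels.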
